A study of Mus musculus with 6 samples.

How the data were processed

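The series measured RNA of sorted mouse Treg in 6 libraries, 3 of GFP+ and 3 of GFP- cells, with the poly(A) protocol in 1 library and the single-cell protocol in 2 libraries of each population. Per the labels' protocols, RNA was purified from sorted cells with a column kit, messenger RNA was taken by poly(A) selection or by a single-cell approach, and libraries followed Illumina protocols. The study's design describes the 3 samples of a population as biologically independent, and p-values measure the spread between these samples.

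The authors deposited raw counts of reads per Entrez gene in one table for the poly(A) and another for the single-cell protocol libraries. The submitters' processing notes name Subread, featureCounts and edgeR and the genome build mm9, without versions, which are not given in the sources used here. Neither these notes nor the labels state whether counting used strand, so reads of genes that overlap or lie antisense to each other may be shared. Per the file headers, both tables also give gene lengths. Of the genes in the single-cell protocol table, 30.9% had a length of exactly 3000 bases and 1 gene a longer one, while 8113 genes were longer than that in the poly(A) table, and how reads of long genes were counted is not stated. The authors also deposited log2 RPKM values per library, which are reads scaled to gene length and library size and, per the file headers, on the log2 scale. Sorted log2 RPKM values were nearly the same in all 6 libraries (median range 0.00335), as after quantile normalisation. These values served only as an alternative to the counts.

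Both count tables held the same 26286 genes. Of these, 540 had no gene symbol and could not be named from the RefSeq table. They held between 0.604% and 4.53% of a library's counts, and they stayed in under their Entrez numbers. Chromosomes were assigned by Entrez number from the RefSeq annotation of assembly GRCm38 for 24176 genes. Since the authors used mm9, no coordinates are given. All columns of the tables belonged to the 6 samples.

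The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the population as group, which left 10523 genes, and libraries were scaled by TMM. TMM factors were 2.02 and 2.06 in the poly(A) libraries and between 0.519 and 0.846 in the others. The quasi-likelihood F-test was fitted to all 6 libraries with the protocol as a covariate, with 3 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all tested genes with a threshold of 0.05, and those of single genes without a named test come from edgeR. Standard errors are those of the fitted log2 fold change, derived from the edgeR F statistic, and CPM are scaled by TMM, except those of genes on chromosomes 3, 8 and 9, which are scaled to all counts of a library. The same fit gave the protocol effect, and a model with an interaction term, with 2 residual degrees of freedom, tested whether the population effect depended on the protocol. A further test used the 4 single-cell protocol libraries alone, and the signs of its called genes were compared with the poly(A) pair.

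The design, the tests, 21 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names Prdm1, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 10 CPM, a symbol that is no clone or locus name, and the same direction in every comparison within a protocol, and for each list up to 5 members with the smallest p. Not every gene that the rule selects is described. Other members are named where they complete a count or stand for those that did not pass. The lists cover naive and central T cell genes, effector Treg transcription factors, suppression genes, activation and costimulatory receptors, tissue homing receptors and integrins, adipose tissue Treg genes, Treg identity genes, follicular Treg genes, helper T cell cytokines, cell cycle, glycolysis, cholesterol synthesis, unfolded protein response, type I interferon response, immediate early genes, and markers of B, plasma, myeloid, CD8 T, natural killer and erythroid cells. They were tested with camera at a preset correlation of 0.01 on the edgeR fit, adjusted by Benjamini-Hochberg over the 21 lists, and again with an estimated correlation and with fry. A second list of 25 macrophage genes, none of them in the 21 lists, and a list of 12 general T cell genes were written after the first results and before their own values were looked at, except for the counts of Cd4.

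Before the libraries were averaged they were compared in pairs: chi-square values of the counts were at least 96.7 per degree of freedom, so no pair matched within sampling noise. The correlation of log2 CPM across genes was 0.961 between GFP- replicates 2 and 5 and 0.980 between GFP+ replicates 1 and 4. It was 0.754 and 0.708 between GFP- replicate 20 and replicates 2 and 5, 0.707 and 0.697 between GFP+ replicate 19 and replicates 1 and 4, 0.937 in the poly(A) pair and from 0.922 to 0.952 between the populations within the single-cell protocol. On simulated counts for the 6 libraries the edgeR test recovered 27% of genes changed 2-fold and 98% of those changed 4-fold, with 7.41% of its calls among unchanged genes. DESeq2 had 13.6% of its calls among unchanged genes. With the 4 single-cell protocol libraries alone edgeR had 10.9%, and it recovered 15% of genes changed 2-fold. The changed genes were drawn only from the more highly expressed ones, so recovery of weakly expressed genes was not measured. Camera found the list that was raised and 0 of 20 lists that were not. The simulated genes were drawn independently of each other, so this does not check camera on lists of correlated genes. Intervals of the poly(A) ratios are exact binomial (Clopper-Pearson) at 95% and cover counting error only.

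Alternatives were DESeq2 1.42.0 as a test and its size factors in edgeR, limma-voom, no filter on low counts, no protocol covariate, a block of consecutive title numbers, the single-cell protocol libraries alone, the poly(A) pair alone, and each library left out in turn. After seeing the data, limma on the deposited log2 RPKM and an unfiltered fit without chromosomes 3, 8 and 9 were added. The single-cell protocol libraries held almost no counts for genes of chromosomes 3, 8 and 9, so the filter removed all of these genes except Pex2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.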

Results

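Regulatory T cells (Treg) are CD4+ T cells that restrain immune responses and depend on the transcription factor Foxp3. Blimp-1, the protein of the gene Prdm1, is a transcriptional repressor found in effector T cells and plasma cells. Mice of the C57BL/6 strain carried a green fluorescent protein (GFP) reporter of Blimp-1. All 6 sample titles carry the prefix BlimpHet, which points to animals heterozygous at the Blimp-1 locus. CD4+ CD25high Treg from the pooled spleens and lymph nodes of these mice were sorted into a GFP+ and a GFP- population. RNA sequencing gave 6 libraries, 3 of each population, which the study's design describes as biologically independent. In each population 1 library was made with standard poly(A) selection (GFP- replicate 20 and GFP+ replicate 19), and 2 with an amplification protocol first devised for single cells and used here on RNA of sorted populations (GFP- replicates 2 and 5, GFP+ replicates 1 and 4). Replicate numbers are those of the sample titles. The poly(A) libraries held 27221562 (GFP-) and 28354321 (GFP+) counts, and the single-cell protocol libraries 16317061 and 15224051 (GFP-) and 17539208 and 17601420 (GFP+). Genes with at least 1 count numbered 18921 and 19118 in the poly(A) libraries and between 13022 and 14186 in the others. The title of the series names the development and maintenance of Treg resident in adipose tissue, with the factors IRF4 and BATF and the cytokine interleukin-33.

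The comparison of GFP+ with GFP- Treg asked which transcripts went with expression of the Blimp-1 reporter. Prdm1 (Entrez 12142) was the check of the labels. It stood at 9.13, 2.46 and 2.66 CPM (counts scaled to library size) in GFP- replicates 20, 2 and 5, against 152, 44.3 and 29.5 CPM in GFP+ replicates 19, 1 and 4. The log2 fold change was 3.93 ± 0.27 (SE, n = 3 per population), and each GFP+ library lay above each GFP- library of its own protocol (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 7.31e-05). The cells were sorted by a reporter of this gene, which can also alter its transcript, so Prdm1 checks the sort and is no independent finding.

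The highest rises in GFP+ Treg included genes known from macrophages. Complement C1q had 3 chains among them: C1qc (Entrez 12262) had a log2 fold change of 6.51 ± 0.37, C1qb (Entrez 12260) 6.42 ± 0.33 and C1qa (Entrez 12259) 6.34 ± 0.34 (SE, n = 3 per population). Csf1r (Entrez 12978), the receptor of the macrophage growth factor CSF1, rose from 2.85, 4.20 and 3.80 CPM in GFP- replicates 20, 2 and 5 to 237, 332 and 295 CPM in GFP+ replicates 19, 1 and 4. Gzmb (Entrez 14939), the cytotoxic protease granzyme B, rose by a log2 fold change of 5.98 ± 0.29, from 2.48, 7.46 and 7.85 CPM to 133, 531 and 520 CPM. In all 6 libraries together, 1032 of 10523 tested genes were higher and 387 lower in GFP+ Treg (1419 genes, 13.5%, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05).

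Other genes among the 12 largest rises included Itgad, an integrin chain of splenic macrophages (log2 fold change 6.38), the lectin gene Fcna (6.21), Treml4, a receptor of myeloid cells (6.19), Slpi, a secreted protease inhibitor (6.19), the iron exporter Slc40a1 (6.18) and the metal transporter Slc11a1 of phagosomes (6.16). Standard errors lay between 0.29 and 0.41, and the adjusted p of the 12 genes between 2.34e-05 and 7.00e-05 (edgeR, Benjamini-Hochberg). For each of the 12 every GFP+ library exceeded every GFP- library of its protocol.

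Among the falls, Igfbp4 (Entrez 16010), which encodes a binding protein of insulin-like growth factors, dropped from 193, 155 and 170 CPM in GFP- replicates 20, 2 and 5 to 4.11, 0.654 and 2.47 CPM in GFP+ replicates 19, 1 and 4 (log2 fold change -6.24 ± 0.49, SE, n = 3 per population). The sortilin family receptor gene Sorcs2 (Entrez 81840) followed at -5.76 ± 0.30. Ccr7 (Entrez 12775), the receptor that guides T cells into lymph nodes, fell by 3.84 ± 0.44 on the log2 scale, and Tcf7 (Entrez 21414), the transcription factor TCF-1 of naive and memory T cells, fell by 3.62 ± 0.32. Bcl2, which blocks cell death, was lower at -3.42 ± 0.34. The remaining members of the 12 largest falls were Gata1, a transcription factor best known from red cell precursors (-4.53), Treml2 (-4.51), Lad1 (-4.49), Nsg2 (-4.17), the dynein chain Dnah7a (-3.61), Ccdc64 (-3.23) and the sodium pump subunit Atp1b1 (-3.17). The adjusted p of these 12 genes ranged from 2.82e-05 to 0.000733 (edgeR, Benjamini-Hochberg), and each GFP+ library lay below each GFP- library of its protocol.

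Of the 1419 genes, 1281 differed by more than 1 on the log2 scale, 962 of them higher and 319 lower in GFP+ Treg. DESeq2, applied to the counts of the same genes, called 1201 higher and 714 lower, which moved the share of higher genes from 72.7% to 62.7%. On simulated counts 13.6% of DESeq2 calls were unchanged genes, against 7.41% with edgeR. Without the protocol covariate edgeR called 115 higher and 24 lower genes (139 in all). Leaving out GFP- replicate 20, GFP+ replicate 19 or GFP+ replicate 1 lowered the total to 722, 703 and 870 genes. The lower genes numbered 138, 141 and 187 without these libraries, 227 without GFP+ replicate 4, 636 without GFP- replicate 2 and 790 without GFP- replicate 5.

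**Figure D1:**
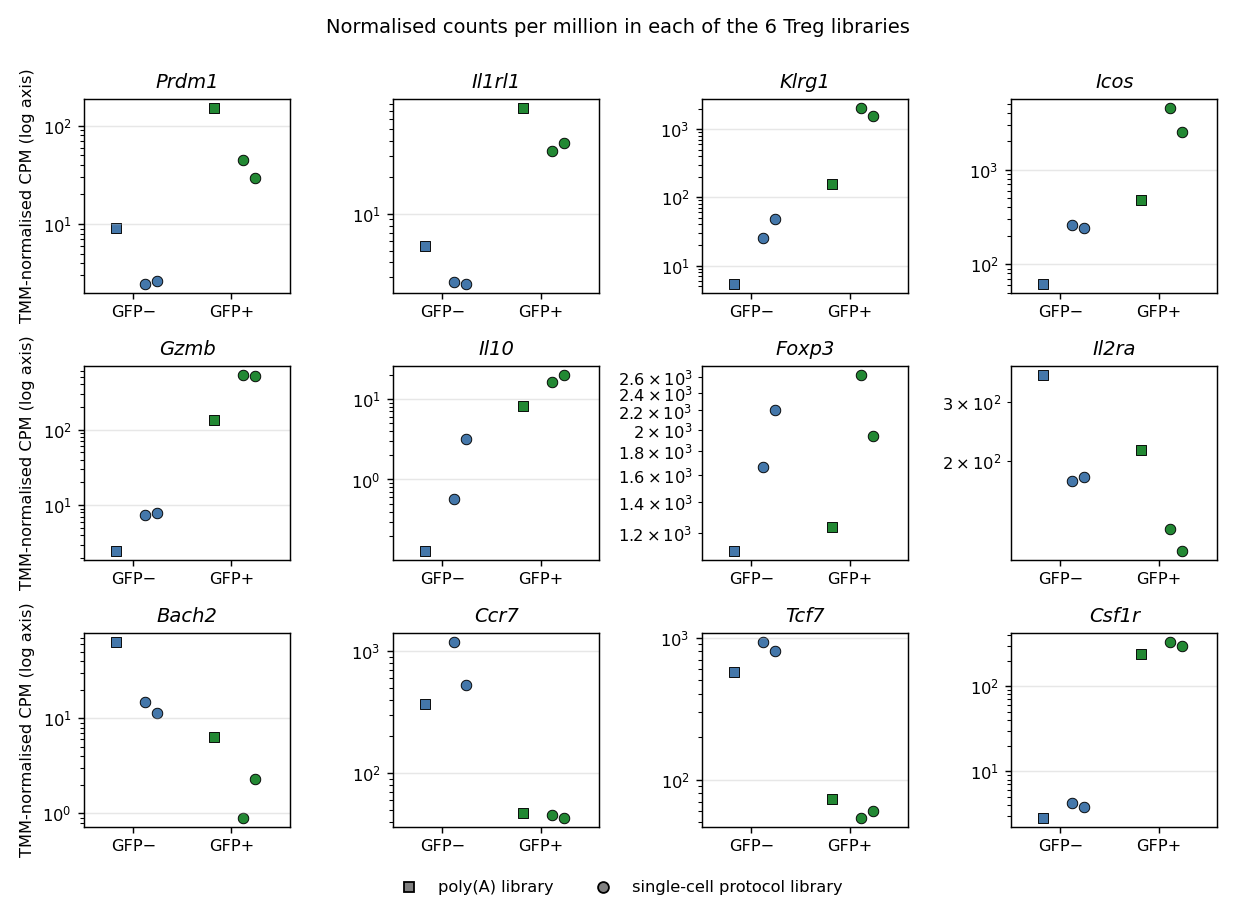
TMM-normalised CPM (log axis, one scale per gene) of 12 genes in each of the 6 libraries, GFP- on the left and GFP+ on the right of each panel. Squares are poly(A) libraries and circles single-cell protocol libraries: Prdm1 stands at 2.46 to 9.13 CPM in GFP- and at 29.5 to 152 CPM in GFP+ libraries, while the Foxp3 values of the populations overlap.

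Genes of naive and central T cells fell together in GFP+ Treg. Of 14 measured members of this list 12 fell and none rose with edgeR (adjusted over the list alone, 13 fell and 1 rose). DESeq2 called 13 lower and 1 higher. Ccr7, described above, stood at 370, 1185 and 524 CPM in GFP- replicates 20, 2 and 5 and at 47.2, 45.2 and 43.2 CPM in GFP+ replicates 19, 1 and 4. Bach2, a repressor of effector genes, fell by 3.14 ± 0.34 and Satb1, a chromatin organiser of T cells, by 2.10 ± 0.33 on the log2 scale. Il7r, the receptor of interleukin-7, had 0.66 ± 0.23 and Ly6c1 -1.36 ± 0.44, both short of the threshold over all genes. The list was lower as a set (camera, adjusted p = 1.61e-18 by Benjamini-Hochberg over 21 lists, and adjusted p = 0.0497 with an estimated correlation). Myeloid markers rose in the same GFP+ libraries, 10 of 11 measured members with a list median of 4.68 on the log2 scale. In all, 12 of the 21 lists passed with camera's preset correlation and 3 with an estimated one, these being the naive and central genes, the effector transcription factors and the myeloid markers. The estimate lay below the preset 0.01 for some lists, among them the effector transcription factors (-0.022), the myeloid markers (-0.012) and the interferon response (-0.082). Their p rose even so, and the weaker calls with an estimated correlation cannot be put down to correlation of genes alone. Other splits of the 6 libraries into 3 and 3 gave up to 13 lists with the preset correlation.

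Transcription factors of effector Treg were higher in GFP+ Treg for 10 of 12 measured genes, with none lower (10 also when adjusted over the list alone). Apart from Prdm1 itself, Pparg, a nuclear receptor of adipose Treg and of macrophages, rose by a log2 fold change of 3.84 ± 0.40, and Ahr, the aryl hydrocarbon receptor, by 2.17 ± 0.23. Pparg levels were low, with 0.217, 0.362 and 0.380 CPM in GFP- replicates 20, 2 and 5. GFP+ replicates 19, 1 and 4 had 4.56, 3.68 and 4.06 CPM. Irf4 and Batf, the factors named in the title of the series, rose by 1.06 ± 0.23 (adjusted p = 0.0150) and 1.32 ± 0.32 (adjusted p = 0.0266, edgeR with Benjamini-Hochberg adjustment, n = 3 per population). Both lay outside the rule for naming genes, so their calls were not checked with a library left out. Tbx21 rose by 1.28 ± 0.24, with an edgeR adjusted p of 0.0598 without GFP- replicate 20 and 0.0657 without GFP+ replicate 19. Hif1a (0.36 ± 0.25) and Bhlhe40 (0.13 ± 0.31) did not pass. The set test gave an adjusted p = 1.41e-09 (camera, Benjamini-Hochberg), or adjusted p = 0.0497 with an estimated correlation, in libraries whose myeloid markers rose by a median of 4.68. Prdm1, whose rise follows from the sort, is among the 10 higher genes and in the set, which was not tested without it.

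Genes of Treg suppression rose for 10 of 13 measured members, and 1 member fell (11 rose and 1 fell adjusted over the list alone). Besides Gzmb, Havcr2, the inhibitory receptor TIM-3 that myeloid cells also carry, rose by a log2 fold change of 5.43 ± 0.39. The cytokine gene Il10 rose by 4.11 ± 0.65, from 0.130, 0.580 and 3.17 CPM in GFP- replicates 20, 2 and 5 to 8.12, 16.3 and 19.8 CPM in GFP+ replicates 19, 1 and 4. The inhibitory receptors Tigit and Ctla4 rose by 3.46 ± 0.38 and 2.09 ± 0.32. Lrrc32, which holds latent TGF-beta on the Treg surface, fell by 2.85 ± 0.28 on the log2 scale. Tgfb1 (1.01 ± 0.32) and Prf1 (-0.21 ± 0.41) did not pass. The list was higher as a set (camera, Benjamini-Hochberg, adjusted p = 2.22e-12), a call that was lost with adjusted p = 0.0873 with an estimated correlation. The myeloid markers rose in these libraries too (10 of 11).

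Receptors of activation and costimulation were higher for 8 of 15 measured genes with edgeR, and none was lower (9 rose and 1 fell adjusted over the list alone). DESeq2 called 9 higher and 1 lower. Klrg1, a lectin-like receptor of terminally differentiated lymphocytes, rose by a log2 fold change of 5.38 ± 0.41, and the costimulatory receptor Icos by 3.52 ± 0.39, to 480, 4522 and 2542 CPM in GFP+ replicates 19, 1 and 4. Cd44, a marker of activated T cells, rose by 1.61 ± 0.25. Il2ra, which encodes CD25 and was used in the sort, had -0.64 ± 0.23 (adjusted p = 0.111, edgeR with Benjamini-Hochberg adjustment). It passed with a block of consecutive title numbers in place of the protocol. The set passed camera with adjusted p = 1.34e-05 (Benjamini-Hochberg), but not with an estimated correlation (adjusted p = 0.152). Myeloid markers rose beside it with a median of 4.68.

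Of the receptors and integrins of tissue homing, 5 of 8 measured members rose and none fell (5 also when adjusted over the list alone). Ccr10, a receptor for chemokines of skin and mucosa, rose from 0.848, 0.362 and 2.15 CPM in GFP- replicates 20, 2 and 5 to 65.3, 56.4 and 55.0 CPM in GFP+ replicates 19, 1 and 4 (log2 fold change 5.90 ± 0.50). Itgae, the integrin chain CD103 that binds epithelial E-cadherin, rose by 4.13 ± 0.37, the chemokine receptor Cxcr3 by 2.03 ± 0.33, and Ccr6 by 1.53 ± 0.25. Gpr15 also rose (1.35 ± 0.28). Its edgeR adjusted p was 0.0731 without GFP- replicate 20, 0.0769 without GFP+ replicate 19 and 0.0657 without GFP+ replicate 1. The set had adjusted p = 1.60e-06 (camera, Benjamini-Hochberg), and adjusted p = 0.0801 with an estimated correlation. Another 10 members lie on chromosomes 3, 8 and 9 and were not tested. Here too the myeloid markers rose in the GFP+ libraries (10 of 11).

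Genes known from adipose tissue Treg rose for 8 of 10 measured members, with none lower (8 also when adjusted over the list alone). Il1rl1, the interleukin-33 receptor ST2, stood at 5.43, 2.75 and 2.66 CPM in GFP- replicates 20, 2 and 5 and at 74.3, 33.0 and 38.2 CPM in GFP+ replicates 19, 1 and 4 (log2 fold change 3.74 ± 0.23, adjusted p = 4.78e-05, edgeR with Benjamini-Hochberg adjustment). Il9r, a cytokine receptor gene, rose by 3.33 ± 0.30 and Areg, the growth factor amphiregulin, by 3.06 ± 0.34. Pparg, Gata3, Nfil3, Il10, Areg and Klrg1 also belong to the lists above, so these counts are not independent of them. Cd36 (0.38 ± 0.58) and Dgat2 (0.46 ± 0.25), genes of lipid uptake and storage, did not pass. The set had adjusted p = 4.23e-14 (camera, Benjamini-Hochberg), and adjusted p = 0.0529 with an estimated correlation, again with myeloid markers higher by a median of 4.68.

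**Figure D2:**
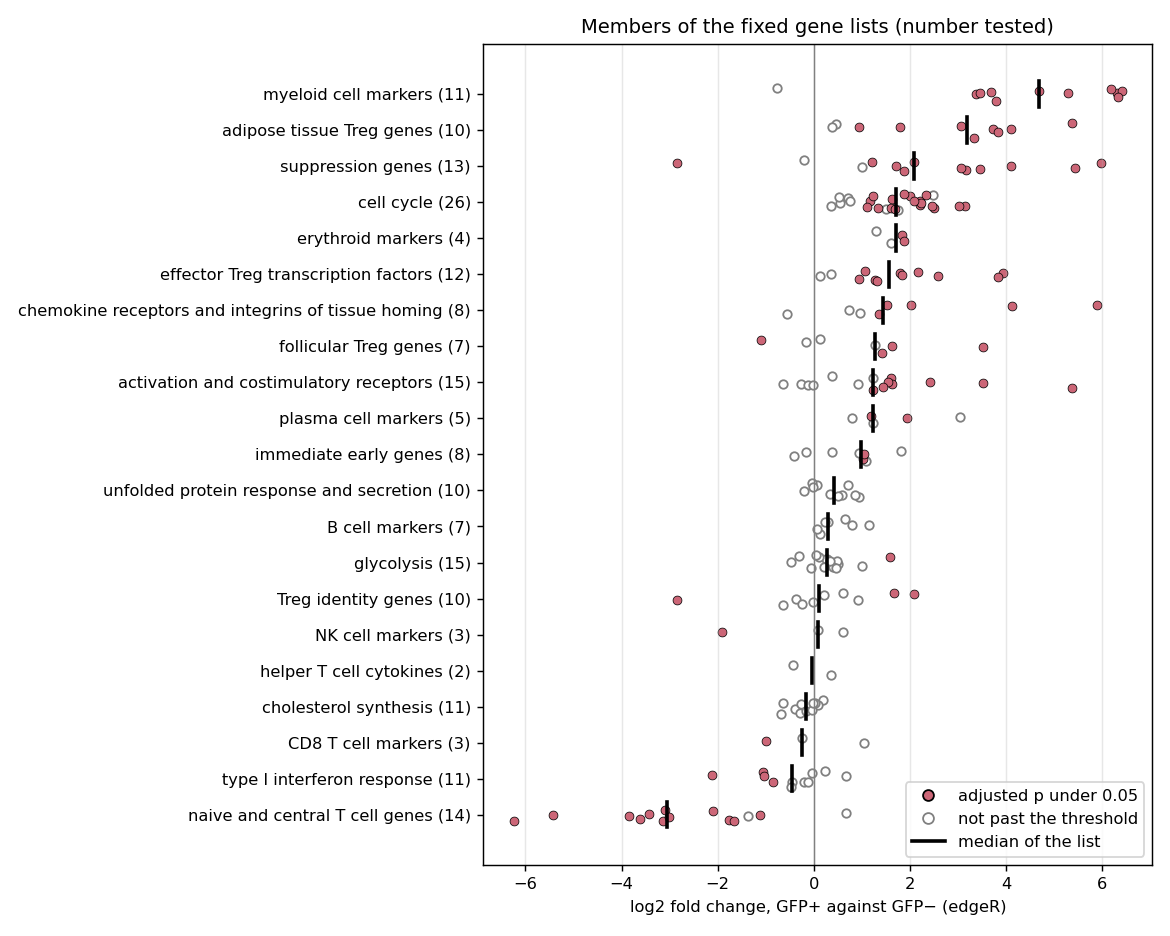
Each point is a member of a fixed gene list, placed by its log2 fold change of GFP+ against GFP- Treg from edgeR (horizontal axis). Filled points have an adjusted p under 0.05, bars are list medians and numbers in brackets are members tested; the medians run from -3.06 for naive and central T cell genes to 4.68 for myeloid cell markers.

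The measured Treg identity genes did not move as a set. Another 4 of the 14 members lie on chromosomes 3, 8 and 9 and were not tested. In the poly(A) pair Gpr83 (log2 ratio -2.80), Folr4 (-0.58) and Nrp1 (-0.27) were lower and Nt5e (0.50) was higher, without a replicate check. Foxp3 had 1097, 1662 and 2210 CPM in GFP- replicates 20, 2 and 5 and 1233, 2624 and 1940 CPM in GFP+ replicates 19, 1 and 4, a log2 fold change of 0.21 ± 0.31 (adjusted p = 0.710, edgeR with Benjamini-Hochberg adjustment). Of 10 measured members Ctla4 and Capg rose and Lrrc32 fell (2 and 1 also when adjusted over the list alone). Capg, an actin-capping protein, had 1.66 ± 0.43 with adjusted p = 0.0348, which became 0.121 without GFP- replicate 20, 0.122 without GFP+ replicate 19 and 0.121 without GFP+ replicate 1. Ikzf2, the transcription factor Helios, had 0.60 ± 0.23 (adjusted p = 0.126, edgeR), and passed with a block of consecutive title numbers in place of the protocol. Camera gave an adjusted p = 0.988 with a negative direction, while the list's median (0.10) and mean (0.14) were positive. The myeloid markers were higher in the same libraries by a median of 4.68.

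Of 7 measured genes of follicular Treg, Icos, Tox2 and Pdcd1 rose and Bcl6 fell (4 rose and 1 fell adjusted over the list alone). Pdcd1, the inhibitory receptor PD-1, had a log2 fold change of 1.63 ± 0.33. Bcl6, the transcription factor of follicular T cells, had -1.10 ± 0.29 (adjusted p = 0.0403), and Tox2 1.41 ± 0.26 (adjusted p = 0.00821, edgeR with Benjamini-Hochberg adjustment). Without GFP- replicate 20 the adjusted p was 0.448 for Bcl6 and 0.122 for Tox2, and without GFP+ replicate 19 it was 0.403 and 0.160. Bcl6 also had 0.12 without GFP+ replicate 1 and 0.0672 without GFP+ replicate 4. The set passed narrowly (camera, Benjamini-Hochberg, adjusted p = 0.0417, adjusted p = 0.284 with an estimated correlation). It had 0.0930 without GFP- replicate 2 and 0.0634 without GFP+ replicate 4, in libraries with raised myeloid markers. Icos and Pdcd1 also belong to the activation list. Cxcr5 and Il21, members that lie on chromosomes 3, 8 and 9, were both lower in the poly(A) pair. Cxcr5 had 160 CPM in GFP- replicate 20 and 66.7 CPM in GFP+ replicate 19 (log2 ratio -1.26), without a replicate check. Of the helper T cell cytokines only Ifng (0.37 ± 0.29) and Tnf (-0.44 ± 0.35) were tested, while 2 of the 12 members lie on chromosomes 3, 8 and 9 and lacked single-cell protocol counts with these chromosomes. Neither passed with edgeR, DESeq2 or limma-voom, nor at an unadjusted p under 0.05 (set adjusted p = 0.988, camera with Benjamini-Hochberg adjustment).

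Cell cycle genes rose together in GFP+ Treg, 18 of 26 measured members with none lower (24 adjusted over the list alone). Ube2c, a ubiquitin-conjugating enzyme of mitosis, rose from 2.80, 12.2 and 11.3 CPM in GFP- replicates 20, 2 and 5 to 19.2, 134 and 105 CPM in GFP+ replicates 19, 1 and 4 (log2 fold change 3.15 ± 0.25). Birc5, the inhibitor of apoptosis survivin, rose by 3.02 ± 0.32, the mitotic kinase Plk1 by 2.50 ± 0.23, and Cdk1, the kinase that drives entry into mitosis, by 2.21 ± 0.22. Mki67, the proliferation marker Ki-67, had 2.48 ± 0.82 (adjusted p = 0.0871, edgeR with Benjamini-Hochberg adjustment), a spread too wide for the threshold. The set had adjusted p = 1.31e-16 (camera, Benjamini-Hochberg), lost with adjusted p = 0.152 with an estimated correlation. The myeloid markers rose beside it (10 of 11).

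Metabolic and secretory lists did not pass as sets, in the same libraries in which the myeloid markers rose. Among 15 genes of glycolysis only Slc16a3, the lactate transporter MCT4, rose (1.59 ± 0.36, adjusted p = 0.0196, edgeR with Benjamini-Hochberg adjustment, 1 member also when adjusted over the list alone). Its adjusted p was 0.0679 without GFP- replicate 20, 0.0780 without GFP+ replicate 19 and 0.0614 without GFP+ replicate 4. Of 11 genes of cholesterol synthesis 0 passed, also adjusted over the list alone, while 2 had an unadjusted p under 0.05 with edgeR and DESeq2 called 1. The lowest p belonged to Sqle, squalene epoxidase (-0.69 ± 0.21, adjusted p = 0.0702). Of 10 genes of the unfolded protein response and secretion 0 passed in either adjustment, while 3 had an unadjusted p under 0.05 with edgeR and DESeq2 called 2. The chaperone gene Hsp90b1 had 0.94 ± 0.30 (adjusted p = 0.0759, edgeR). With a block of consecutive title numbers in place of the protocol, Sqle and Hsp90b1 both passed. Camera's adjusted p was 0.345 for glycolysis, 0.345 for cholesterol synthesis and 0.332 for the unfolded protein response (Benjamini-Hochberg).

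Of 11 measured genes of the type I interferon response 4 fell and none rose (4 also when adjusted over the list alone). Usp18, a negative regulator of interferon signalling, fell by 2.13 ± 0.26 on the log2 scale (adjusted p = 0.00102, edgeR with Benjamini-Hochberg adjustment). Oasl2 (-1.06 ± 0.27), Ifit1 (-0.84 ± 0.22) and Ifit2 (-1.04 ± 0.27), effectors of antiviral defence, passed by less. Without GFP- replicate 20 or GFP+ replicate 19, 1 or 4 the adjusted p of these 3 genes lay between 0.0673 and 0.240, and without GFP- replicate 2 it was 0.0529 for Ifit1 and 0.0836 for Ifit2. The set had adjusted p = 0.0417 (camera, Benjamini-Hochberg), and adjusted p = 0.225 with an estimated correlation. It had 0.0526 without GFP- replicate 2, 0.0512 without GFP+ replicate 1 and 0.0737 without GFP+ replicate 4. Of 8 immediate early genes the heat shock genes Hspa1a (1.03 ± 0.25) and Hspa1b (1.05 ± 0.28) rose (4 rose adjusted over the list alone), near-identical copies whose reads cannot be well told apart. Without GFP- replicate 20 or GFP+ replicate 19, 1 or 4 their adjusted p lay between 0.0625 and 0.496, and Hspa1b had 0.0640 without GFP- replicate 2. The set did not pass (camera, Benjamini-Hochberg, adjusted p = 0.250). Myeloid markers rose in the same libraries by a median of 4.68.

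Markers of other cell types moved apart from each other. Of 11 measured myeloid markers 10 rose (10 also when adjusted over the list alone), with a median log2 fold change of 4.68 and adjusted p = 4.25e-36 (camera, Benjamini-Hochberg), and adjusted p = 0.0186 with an estimated correlation. Emr1, which encodes the macrophage antigen F4/80, rose from 1.48, 1.81 and 1.52 CPM in GFP- replicates 20, 2 and 5 to 56.6, 66.2 and 68.7 CPM in GFP+ replicates 19, 1 and 4. Lyz2, the lysozyme of myeloid cells, rose by 3.68 ± 0.31 and Cd68 by 4.68 ± 0.33. Siglech, a marker of plasmacytoid dendritic cells, had -0.76 ± 0.46 (adjusted p = 0.337, edgeR with Benjamini-Hochberg adjustment). Of 7 B cell markers 0 passed in either adjustment with edgeR, 3 had an unadjusted p under 0.05 and DESeq2 called 1. The B cell list had an adjusted p = 0.271 (camera, Benjamini-Hochberg), with Cd22, an inhibitory receptor of B cells, at 0.79 ± 0.31.

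Of 5 plasma cell markers Tnfrsf13b (1.18 ± 0.25) and Sdc1, syndecan-1 (1.95 ± 0.52), rose (3 adjusted over the list alone), in libraries with raised myeloid markers. Without GFP- replicate 20, GFP+ replicate 19 and GFP+ replicate 1 the adjusted p was 0.221, 0.241 and 0.0792 for Tnfrsf13b and 0.242, 0.275 and 0.0869 for Sdc1, which had 0.0958 without GFP+ replicate 4 (edgeR, Benjamini-Hochberg). Igj, the joining chain of secreted antibodies, had 3.03 ± 1.00 and 136 CPM in GFP+ replicate 4 against 8.75 CPM in GFP+ replicate 1. The set had adjusted p = 0.0417 (camera, Benjamini-Hochberg), and adjusted p = 0.410 with an estimated correlation. It had 0.102 without GFP- replicate 2 and 0.0896 without GFP+ replicate 4.

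Of 4 erythroid markers the alpha-globin copies Hba-a1 (1.83 ± 0.42) and Hba-a2 (1.87 ± 0.44) rose (4 adjusted over the list alone), paralogs whose reads could be split by the counting, and the myeloid markers rose with them. Their adjusted p without GFP+ replicate 1 was 0.0639 and 0.0673, and without GFP+ replicate 4 it was 0.0510 and 0.0595 (edgeR, Benjamini-Hochberg). Hba-a2 had 0.0513 without GFP- replicate 20 and 0.0528 without GFP+ replicate 19. The set had adjusted p = 0.0329 (camera, Benjamini-Hochberg), adjusted p = 0.458 with an estimated correlation and 0.0634 without GFP+ replicate 4. Of 3 CD8 T cell markers Cd8a fell (-0.99 ± 0.23, adjusted p = 0.0220, 1 also when adjusted over the list alone). Without GFP- replicate 20, GFP+ replicate 19, 1 and 4 its adjusted p was 0.222, 0.220, 0.0929 and 0.0906. Of 3 natural killer cell markers Ncr1, the receptor NKp46, fell (-1.92 ± 0.45, adjusted p = 0.0219, 1 also when adjusted over the list alone), with 0.0578, 0.0558 and 0.0635 without GFP- replicate 20, GFP+ replicate 19 and GFP+ replicate 1. Camera gave an adjusted p = 0.50 for both lists (Benjamini-Hochberg), and the natural killer list had a median of 0.10 beside a mean of -0.40.

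Some genes central to these lists were measured in the poly(A) libraries alone. Maf, a transcription factor of interleukin-10 producing T cells, had 202 CPM in GFP- replicate 20 and 1737 CPM in GFP+ replicate 19, a log2 ratio of 3.10 (interval 3.06 to 3.15). Ccr2, a receptor of inflammatory chemokines, went from 5.00 to 157 CPM (log2 ratio 4.97, interval 4.73 to 5.23), Ccr8, found on tissue Treg, from 43.7 to 177 CPM (2.02, interval 1.93 to 2.11) and Cxcr6 from 17.1 to 101 CPM (2.56, interval 2.42 to 2.71). Lef1, a partner of TCF-1, had 191 and 91.4 CPM (-1.07, interval -1.13 to -1.0), and Gpr83, a receptor enriched in Treg, 248 and 35.5 CPM (-2.80, interval -2.90 to -2.71). These values are CPM scaled to all counts of a library, the exact binomial intervals (95%) cover counting error only, and with 1 library per population the differences had no replicate check. The myeloid markers rose in the same poly(A) GFP+ library.

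In the single-cell protocol libraries, 3507 genes that the RefSeq annotation of assembly GRCm38 places on chromosomes 3, 8 and 9 were without counts, apart from Pex2 and Hnf4g. Of the 1810 of these genes with at least 100 poly(A) counts 1 had a single-cell protocol count (0.0552%), against 9948 of 9968 (99.8%) on the other chromosomes. Chromosomes 3, 8 and 9 carried 14.5% of the poly(A) counts, and their genes, among them Cd3e, Klf2, S1pr1 and Nrp1, are not part of the tests, with Pex2 the exception.

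**Figure D3:**
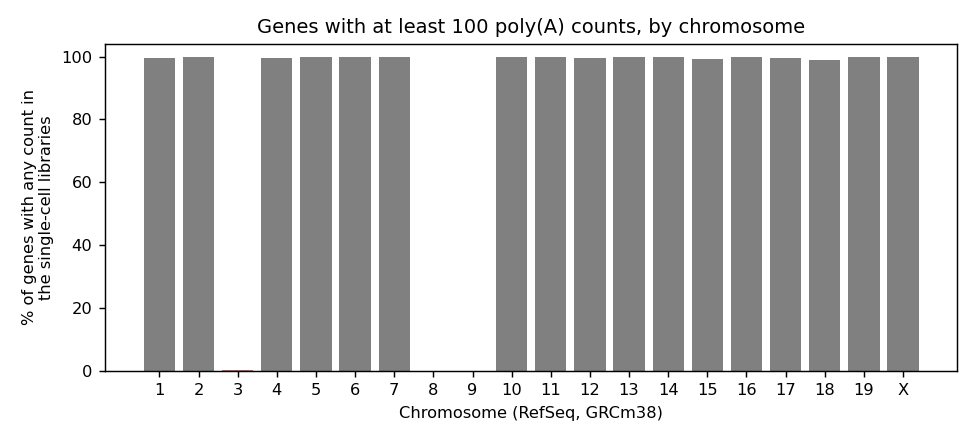
Bars give, for each chromosome (RefSeq annotation, GRCm38), the percentage of genes with at least 100 counts in the poly(A) libraries that had any count in the 4 single-cell protocol libraries. Chromosome 3 stands at 0.185% and chromosomes 8 and 9 at 0, while the other chromosomes lie close to 100.

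The mRNA protocols differed far more than the populations. Ribosomal protein genes took 3.12% and 1.68% of the counts in poly(A) GFP- and GFP+ libraries, against 18.3% and 25.2% (GFP- replicates 2 and 5) and 13.8% and 14.5% (GFP+ replicates 1 and 4) with the single-cell protocol. Actg1, which encodes gamma-actin, was lower in poly(A) libraries by 2.42 ± 0.38 on the log2 scale, a gene chosen after its values were seen. In all, 6854 of 10523 genes differed between the protocols, 3643 higher and 3211 lower in the poly(A) libraries (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 2 against 4 libraries). The count fell to 4400 without GFP- replicate 20 and to 4215 without GFP+ replicate 19. The single-cell protocol table gave a length of 3000 bases for 30.9% of genes, and whether long genes were counted over the same length in both protocols is not stated.

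Whether the population difference itself depended on the protocol was tested as an interaction. Prdm1, with a log2 fold change of 3.84 in the single-cell protocol libraries and a log2 ratio of 4.09 in the poly(A) pair, was an example of similar size in both. The interaction test called 0 of 10523 genes with edgeR and 0 with DESeq2, while 24 and 13 genes had an unadjusted p under 0.05. On simulated counts the test recovered 0 of 100 genes whose population effect differed 4-fold between protocols, so differences of that size were not detectable with these 6 libraries.

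The genes called in the single-cell protocol libraries alone were carried over to the poly(A) pair, with which they share no library. The 4 libraries called 711 of 10236 genes, 567 higher and 144 lower in GFP+ Treg (edgeR, Benjamini-Hochberg, 2 against 2 libraries). On simulated counts 10.9% of the calls of this test were unchanged genes. Of the 711 genes, 709 (99.7%) had the same sign in the poly(A) pair. The exceptions were Actn2, a muscle alpha-actinin (2.47 against -0.48), and the histone gene Hist1h2bb (2.53 against -0.38). The median change of the higher genes was 2.85 on the log2 scale in the single-cell protocol libraries and 2.49 in the poly(A) pair, and that of the lower genes -2.46 and -2.02. Across the called genes, which are not independent replicates, the correlation was 0.94, and genes that were not called had the same sign in 82.7% of cases. The myeloid gene Csf1r was among those higher in both.

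**Figure D4:**
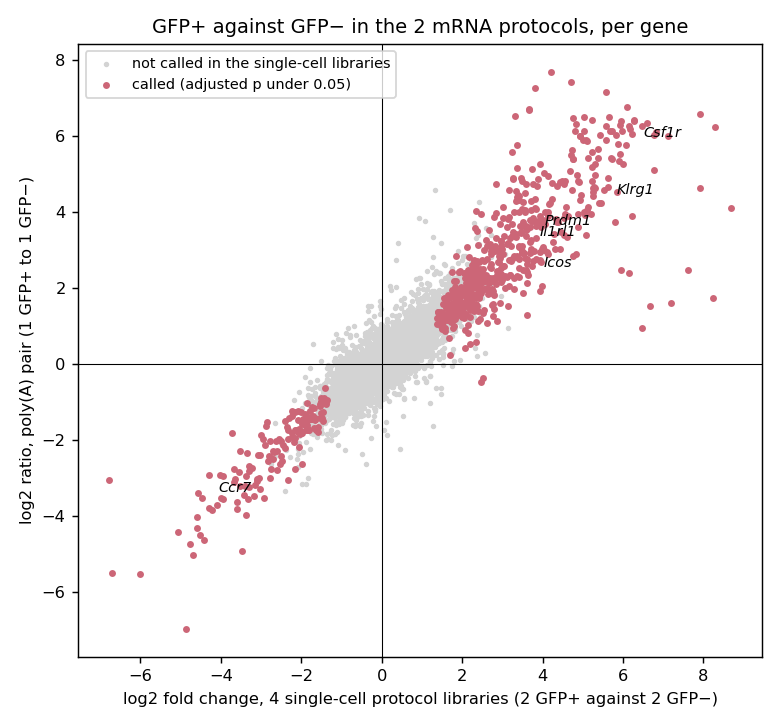
Each point is a gene, with its log2 fold change of GFP+ against GFP- Treg in the 4 single-cell protocol libraries (horizontal axis) and its log2 ratio in the poly(A) pair (vertical axis). Coloured genes were called in the single-cell protocol libraries; 709 of these 711 have the same sign on both axes.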

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

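The tests of why chromosomes 3, 8 and 9 lacked counts were chosen after the result was seen.

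Several genes of chromosomes 3, 8 and 9 carried strong signals in the poly(A) pair, data that the tests above do not use, and they are given because their ratios of GFP+ to GFP- were the highest among genes of these chromosomes with a mean of at least 10 CPM. Their CPM are scaled to all counts of a library. Cd5l, which encodes a secreted protein of tissue macrophages, went from 1.29 CPM in GFP- replicate 20 to 85.6 CPM in GFP+ replicate 19 (log2 ratio 6.06). Vcam1, an adhesion molecule of stroma and of splenic macrophages, went from 3.49 to 189 CPM (5.76), Hmox1, the haem-degrading enzyme, from 6.91 to 248 CPM (5.17), and Trf, the iron carrier transferrin, from 5.73 to 259 CPM (5.50). Ccr3, a chemokine receptor best known from eosinophils, had a log2 ratio of 5.58 (0.918 to 43.8 CPM) and the adhesion molecule Cadm1 5.58 (0.514 to 24.6 CPM). Paqr9 (6.32, 0.257 to 20.6 CPM) and Ky (5.80, 0.698 to 38.8 CPM) completed the set. With 1 library per population these ratios had no replicate check, and the myeloid markers of other chromosomes rose in the same GFP+ library.

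Chromosomes 3, 8 and 9 were without counts in all 4 single-cell protocol libraries, apart from Pex2 and Hnf4g. The counts argue against lower depth or sensitivity of these libraries, since 99.8% of the genes of other chromosomes with at least 100 poly(A) counts had a single-cell protocol count. A step of alignment or counting that left these chromosomes out remains a candidate explanation: 0.0552% of their genes with at least 100 poly(A) counts had a count there. The pattern covers both populations alike.

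Insig1, a regulator of sterol synthesis, stood out because its poly(A) log2 ratio was 0.037 (30.9 TMM-normalised CPM in GFP- replicate 20 and 31.7 CPM in GFP+ replicate 19), while both GFP+ single-cell protocol libraries (4.99 and 6.16 CPM) lay below both GFP- ones (7.83 and 7.47 CPM). The test of an interaction of protocol and population called 0 genes, and on simulated counts it recovered 0 of 100 genes with a 4-fold difference. Insig1 did not pass between populations (log2 fold change -0.27 ± 0.23, adjusted p = 0.510, edgeR with Benjamini-Hochberg adjustment).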

How the results depend on the processing

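The test of a shared preparation, the fit to the deposited log2 RPKM and the unfiltered fit without chromosomes 3, 8 and 9 were chosen after the results were seen. The populations share no replicate numbers in the labels, so the main tests used no pairing. A block of consecutive title numbers, which the labels do not give as pairs, was run as an alternative below.

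The direction of Prdm1 held in all settings tried, with log2 fold changes from 3.58 to 4.09, and it lost its call only without the protocol covariate (3.97, adjusted p = 0.132, edgeR with Benjamini-Hochberg adjustment). Total, higher and lower genes numbered 2500, 1682 and 818 without the low-count filter (21218 genes tested), 2409, 1594 and 815 when chromosomes 3, 8 and 9 were also left out, 139, 115 and 24 without the protocol covariate, and 711, 567 and 144 in the single-cell protocol libraries alone. DESeq2 called 714 lower genes. Its size factors in edgeR gave 1411, 979 and 432, limma-voom 1495, 1074 and 421, and limma on the deposited log2 RPKM 1468, 922 and 546. Of the 1419 genes, 1418 were shared with DESeq2, 1386 with limma-voom and 695 with the single-cell protocol libraries alone, all with the same sign. With 1 library left out the total ran from 703 to 2015, the higher from 562 to 1225 and the lower genes from 138 to 790; it was lowest without GFP- replicate 20 (722), GFP+ replicate 19 (703) or GFP+ replicate 1 (870) and highest without GFP- replicate 5 (2015). Without a poly(A) library the other is fitted by its own protocol term, so these fits rest on the single-cell protocol libraries. Without the protocol covariate 42 of the 108 genes selected for naming lost their calls, and in the single-cell protocol libraries alone 16 did, and the cause was not tested.

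With an estimated correlation 3 lists passed. By fry the unfolded protein response passed (adjusted p = 0.0174) and plasma and erythroid markers did not (0.0973 each). The follicular list also failed without the filter (0.408), with limma-voom (0.0510) and without the protocol covariate (0.159), and without the filter glycolysis (0.0380) and the unfolded protein response (0.0362) passed. Of 10 splits of the 6 libraries into 3 and 3, 3 gave as many lists with the preset correlation (12 in the real split, 13 the highest other). For genes 1 did, the real one (1419, highest other 0), but 10 splits are too few for a share under 0.05. Every other split mixes the populations in each group, so their difference widens its spread. The 0 genes there are therefore no support for the real split. The protocol comparison called 10837 genes without the filter and from 4215 to 7109 with 1 library left out. The interaction test also called 0 with DESeq2, with its size factors, without the filter and without each single-cell protocol library, which shows no stability, as it recovered 0 of 100 simulated genes with a 4-fold difference. The share of genes with the same sign in the poly(A) pair ran from 98.96 to 99.89% with 1 single-cell protocol library left out.

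Directions turned only for genes and lists that did not pass, and the cause was not tested. With 1 library left out, Cd79a ran from -0.095 to 0.55, Ms4a1 from -0.15 to 0.48, Cd8b1 from -0.52 to 0.12 and Klrb1c from -0.57 to 0.44 on the log2 scale. Klrb1c was also at -0.071 with limma-voom, -0.051 with the block and -0.20 with the deposited log2 RPKM. The Treg identity list pointed up with adjusted p 0.977 (DESeq2 size factors), 0.778 (limma-voom), 0.996 (block), 0.945 (single-cell protocol libraries alone), 0.618 (fry), 0.919 and 0.877 (without GFP- replicate 20 and GFP+ replicate 19) and 0.766 (without GFP+ replicate 4). With another library left out it pointed down, with 0.992 the highest. Helper T cell cytokines turned up with 0.559 (no filter), 0.956 (limma-voom), 0.951 (no covariate), 0.773 (fry) and 0.869 (without GFP- replicate 2), and had from 0.778 to 0.992 with 1 library left out. Natural killer markers turned up without the filter (0.670).

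A block of consecutive title numbers (1 with 2, 4 with 5, 19 with 20) in place of the protocol gave 2921 genes, 1658 higher and 1263 lower, among them all 1419, and 18 of the 108 genes selected for naming gained a call, among them Il2ra, Ikzf2, Sqle and Hsp90b1. Across 5791 genes the difference between the GFP- single-cell protocol libraries correlated with that between the GFP+ ones (r = 0.57). Neither GC content and gene length (r = 0.65 after adjustment in 5434 genes, 0.57 before) nor immunoglobulin, haemoglobin and ribosomal protein genes (r = 0.57 without them) account for it. A shared preparation of libraries 1 and 2 and of 4 and 5 may, which the labels leave open.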

Other observations

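Both tests of a general fall in sort purity were chosen after the result was seen, and the lists of macrophage and T cell genes below were written after the myeloid markers had been seen.

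Most general T cell genes kept close levels in both populations. Their list held T cell receptor signalling and surface genes, 11 of them measured, with a median log2 fold change of -0.18. Cd4 had 0.021 ± 0.25, the signalling adaptor Lat -0.21 ± 0.29 and the kinase Lck -0.35 ± 0.38, none of them past the threshold (adjusted p = 0.970, 0.686 and 0.604, edgeR with Benjamini-Hochberg adjustment). In the poly(A) pair, Cd3e, a chain of the T cell receptor complex, had 748 CPM in GFP- replicate 20 and 860 CPM in GFP+ replicate 19, and Cd3d had 389 and 355 CPM, all scaled to all counts of a library.

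Genes of macrophages were high in all 3 GFP+ libraries, although the cells had been sorted for CD4 and CD25. The tables argue against a fall in sort purity that raised the markers of all other cell types alike. The 13 markers of B, CD8 T and natural killer cells had a median log2 fold change of 0.22 (quartiles 0.077 and 0.66). Plasma cell (median 1.23) and erythroid markers (1.72) rose more. Their lists rose by camera with the preset correlation but not with an estimated one (adjusted p = 0.410 and 0.458) or by fry. Together the 22 markers had a median of 0.79 and an upper quartile of 1.28, under the lower quartile of the myeloid markers (3.57). Fold changes also depend on each marker's level in GFP- cells. These values do not address a fall in purity that let in some cell types more than others. Macrophages among the sorted GFP+ cells are a candidate explanation, since 16 of 19 measured genes of a second macrophage list were higher (84.2%), and 5 of the 19 also exceeded 10 CPM in GFP- cells. Of its genes with the highest mean CPM over all libraries, Ctsb had 741, 556 and 426 CPM in GFP+ replicates 19, 1 and 4, while Lipa (54.6, 74.1 and 99.4 CPM) was not higher, and its 67.7, 95.5 and 107 CPM in GFP- replicates 20, 2 and 5 would hide a small share of macrophages. Transcription of these genes by GFP+ Treg themselves cannot be told apart from it, as general T cell genes had a median of -0.18 (quartiles -0.46 and 0.16), a value that a small share of macrophages or none would both give, and pooled RNA does not assign transcripts to cells.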
